A study of Alteromonas macleodii with 12 samples.

How the data were processed

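Transcript abundance was measured by RNA sequencing in cultures of Alteromonas macleodii strain 83-1, a marine bacterium. Cultures grew in seawater minimal medium with either 0.06% glucose or a mix of laminarin, alginate and pectin at 0.02% each. Biomass was sampled after 13 h (T1) and 21 h (T2). Per the labels' protocols, total RNA was freed of DNA, depleted of ribosomal RNA, fragmented chemically and made into libraries with a TruSeq RNA kit. The 12 libraries fall into 4 groups of 3 (glucose at T1, glucose at T2, mix at T1, mix at T2), which the labels call triplicates.

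FastQC 0.11.2, Trim Galore 0.4.1, kallisto 0.43.0 and DESeq2 1.14.0 are listed by the submitters' processing notes, without settings. Per the labels, transcript counts came from matching reads to the gene sequences of the strain's own genome. Whether strand was used, and how reads shared by near-identical loci were divided, is not given in the sources used here, so loci with close copies are uncertain.

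The values used are 4 tables of comparisons between groups, each with 4223 loci. The signal column deposited by the authors is the mean normalized count of a locus over the libraries, and it was identical in all 4 tables. Per the file headers, the other columns are the log2 fold change, its standard error on the log2 scale, a Wald score, and a p-value with its adjusted p-value. The deposited score equalled the log2 fold change divided by its standard error in every row, to within 2.34e-13. The deposited adjusted p-values equalled a Benjamini-Hochberg adjustment over the 4221 loci that had a p-value, to within 1.25e-15, and the 2 loci without one were left out of all counts of calls. The fold changes of the 4 tables closed a circle through the 4 groups to within 0.0152 on the log2 scale, as 1 joint fit of all groups gives. The model formula, any filter, and whether fold changes were shrunk toward 0 are not given in the sources used here. The largest standard error was 1.26, at loci with mean normalized counts down to 0.750. Values per library were not used here, so no spread between single libraries could be examined. The labels number the libraries of both time points alike, so libraries with the same number may come from the same flask, and how the deposited fit treated this is not given in the sources used here. The labels do not say how the triplicate cultures were started. The p-values measure the spread between these samples, which may be partly technical.

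The headers name the pair of groups in each table but not which one was subtracted. The direction was read from the standard errors. At a given dispersion, the group with fewer counts has the larger variance. With the first-named group minus the second, the group with the lower level had the larger variance in 100% of the 2646 loci and of the 1310 loci whose levels differed more than 2-fold in the 2 pairs of groups that can be separated. With the other sign it did so in 0%. The fitted and observed variance differences correlated across 4134 loci with r = 0.999 and r = 0.997 under the first sign, and with r = 0.405 and r = 0.288 under the other. All fold changes are given here as mix minus glucose and as T2 minus T1, so the deposited signs were turned. The sign choice was right in both directions of simulated data, and the scale factors below were recovered with errors of at most 1.96%. The simulated data were drawn from the same variance formula that was fitted. They check the computation, not whether the formula holds for the real libraries.

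Group levels were computed from the mean normalized count and the fold changes, with equal weight per group. They are estimates without an error of their own, and any shrinkage would pull groups of weak loci together. The total count per library is not in the tables used. The standard errors gave an estimate per group of the counts per library of about 28800000 for glucose at T1, 23200000 for glucose at T2, 27000000 for the mix at T1 and 26700000 for the mix at T2. The median dispersion was 0.0123 over 4135 loci with a mean normalized count of at least 50, a coefficient of variation between libraries of 11.1%. The median standard error of a log2 fold change lay between 0.142 and 0.146 in the 4 tables.

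A locus was called at an adjusted p under 0.05 in the authors' deposited DESeq2 Wald test, as fixed before the data were examined for the case of comparison tables alone. The difference between the medium effects at T1 and T2 was tested with z, the difference of the 2 log2 fold changes over the root of the summed squares of their standard errors, with a two-sided normal p and Benjamini-Hochberg adjustment over 4221 loci. Those 2 tables share no library. In data simulated for 4223 loci, 100 loci were changed by a log2 of 1 and 100 by 0.5. The z test called 83% and 29% of them, in this order, and 3.45% of its calls were unchanged loci. The simulation took the deposited standard errors as right, and it changed far fewer loci than were called in the real data. These percentages therefore do not carry over to the real calls.

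Neighbouring loci were taken from the serial numbers in the locus tags, which run to 4228 with 5 numbers absent from the tables, on the assumption that they follow the order on the genome. A run was at least 5 loci called in 1 direction with an absolute log2 fold change of at least 1 and with at most 1 other locus between members. The number of runs was set against 1000 shuffles of the order. All 6 runs planted on a simulated background without other calls were found. With none planted no locus was called, so the 0 runs found there were certain and do not measure runs that arise by chance.

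The files do not pair the locus tags with gene names, and 0 of the 4223 tags matched the gene table given for the species, which lists 3963 genes of another strain. The 24 gene lists fixed before the data were examined therefore could not be tested. The rule for named loci, fixed at the same time, allows 2 tags that rose and 2 that fell where names are missing. It was applied to each comparison as the largest log2 fold changes among called loci with a mean normalized count of at least 50. Runs are described by their first and last serial number. All runs at T1 are given, and otherwise the 3 with the largest summed change in each direction, a choice made after the values were seen.

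Alternatives fixed beforehand were an adjusted p under 0.01, an absolute log2 fold change of at least 1 or 2, adjustment over every locus with a p, a mean normalized count of at least 50, a median fold change set to 0, Benjamini-Yekutieli adjustment, the difference taken from the tables over time, and runs without gaps. Total-count scaling was added after seeing the data, because the estimated sums of normalized counts differed between groups. It shifted the fold changes so that the group totals were equal. The shift moved the median log2 fold change from 0.03 to -0.33 for the media at T1, from 0.05 to 1.15 for the media at T2, from 0 to 0.37 for time in the mix and from 0.03 to -1.06 for time in glucose. The covariance that measurement error in shared libraries alone gives was drawn from 100 simulations of unchanged groups with the estimated variances. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.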

Results

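The transcriptome of Alteromonas macleodii 83-1 was compared between a mix of 3 polysaccharides and glucose at 2 times of growth. Laminarin is a storage glucan of brown algae and diatoms, alginate is a cell wall polymer of brown algae, and pectin is a galacturonic acid-rich cell wall polymer. Each of the 4 groups (glucose or mix, at 13 h or 21 h) had 3 libraries. The estimated depth was between about 23200000 and 28800000 counts per library, by group. The median locus had a mean normalized count of 1425 in the authors' deposited table, and 88 of 4223 loci were below 50. The loci carry tags without gene names, so that regions of neighbouring loci are described by serial number and functions are left open.

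The first comparison asks which transcripts depended on the carbon source at T1. Some of the loci with at least a 2-fold medium effect lay in runs of neighbours. Alt831_03772 and Alt831_03777 had the largest rises in the mix in the authors' deposited table, with log2 fold changes of 7.79 (SE 0.28, adjusted p = 1.56e-164) and 7.39 (SE 0.20, adjusted p = 5.99e-287). The largest falls in the authors' deposited table were those of Alt831_03783 (log2 fold change -5.54, SE 0.59, adjusted p = 2.99e-19) and Alt831_03784 (log2 fold change -5.34, SE 0.44, adjusted p = 1.99e-31). Runs of loci higher in the mix numbered 8, with 53 loci, and runs lower in the mix numbered 6, with 45 loci. This split depended on scaling. With the group totals set equal there were 6 higher runs with 41 loci and 13 lower runs with 98 loci.

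Loci 3776 to 3780 had the largest median rise of the 8 runs higher in the mix at T1, a log2 of 6.13 (range 2.18 to 7.39). They were directly followed by loci 3781 to 3785, which were lower in the mix by a median log2 of -4.45 (range -5.54 to -1.70). Loci 4035 to 4040 were higher by a median of 3.22 (range 1.56 to 6.58). In loci 338 to 347, 9 members were called, with a median of 3.04 (range 1.04 to 3.46). The locus between them, Alt831_00341, had a log2 fold change of 3.28 (SE 0.68) but no p-value in the authors' deposited table. Its standard error was far above the median of 0.142 for this comparison. Why it has no p-value is not given in the sources used here, so its rise is uncertain. Loci 2422 to 2431 (median 2.32), 2415 to 2419 (median 1.63), 941 to 949 (median 1.79), 3859 to 3863 (median 1.56) and 3657 to 3661 (median 1.42) made up the rest.

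Besides 3781 to 3785, the runs lower in the mix at T1 were loci 4133 to 4144 (11 members, median log2 fold change -2.56), 4187 to 4194 (median -2.11), 3815 to 3820 (median -2.001), 713 to 720 (median -1.76) and 1997 to 2007 (median -1.48). None of these 14 medians changed sign under total-count scaling. They could not, since each member differed by a log2 of at least 1 and the shift at T1 was 0.362. The runs held 31.3% of the 313 loci called with at least a 2-fold change, and shuffled orders gave a mean of 0.006 runs and at most 1.

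By the authors' deposited table, 1645 of 4221 loci (39.0%) were called at T1, 925 higher and 720 lower in the mix. With at least a 2-fold change, 148 loci were higher and 165 lower in the authors' deposited table. The split depended on scaling. With the group totals set equal, 252 of 2424 calls were higher in the mix.

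**Figure D1:**
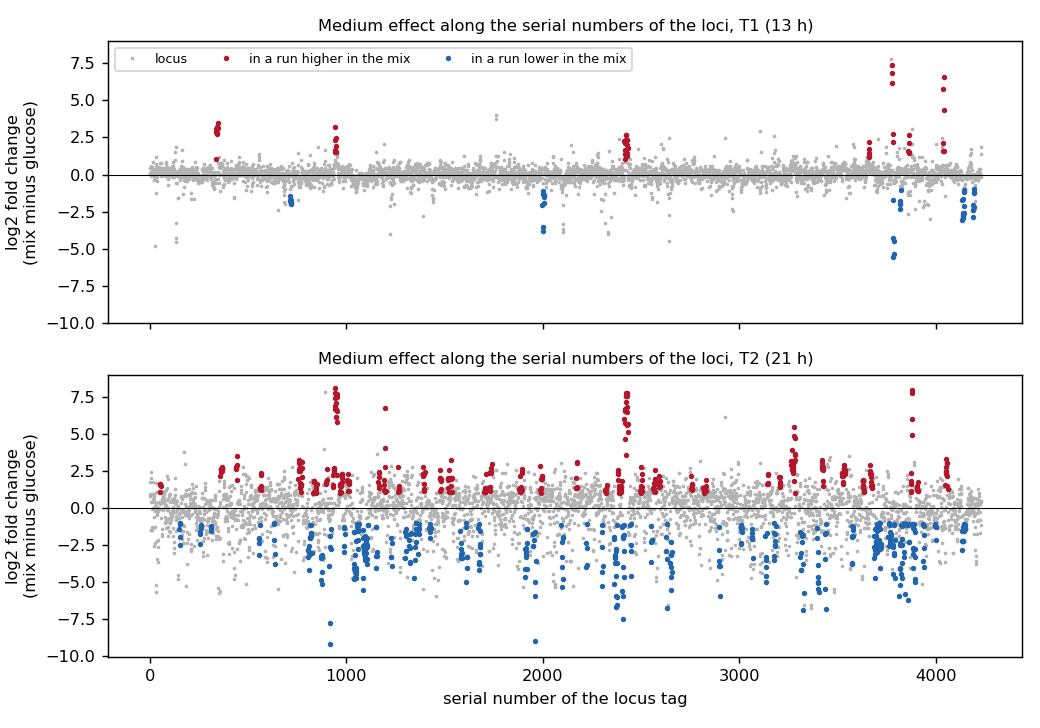
Log2 fold change of mix minus glucose (vertical axes) against the serial number of the locus tag (horizontal axis) at T1 (top) and T2 (bottom), 1 grey point per locus, with loci in runs higher in the mix in red and lower in blue. At T1 the 14 runs stand out from a narrow band, and at T2 there were 108 runs and a wider band.

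At T2 the same contrast asks for the dependence on the carbon source later in growth. Here the runs with the largest summed effect were 2 long regions higher in the mix. All 18 members of the run from 2415 to 2432 were higher, by a median log2 of 6.54 (range 3.57 to 7.76), and their median level was 41098 normalized counts in the mix against 585 in glucose. Loci 932 to 955, with 21 members, were higher by a median of 6.15 (range 1.39 to 8.11), though they did not move alike with time. Loci 3263 to 3278, with 16 members, were higher by a median of 2.89 (range 1.85 to 5.45). In the authors' deposited table, Alt831_00942 (log2 fold change 8.11, SE 0.48, adjusted p = 2.48e-62) and Alt831_03878 (log2 fold change 7.96, SE 0.46, adjusted p = 2.58e-67) had the largest rises.

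Transcripts that were lower in the mix at T2 were led by Alt831_00918 (log2 fold change -9.16, SE 0.39, adjusted p = 2.06e-118) and Alt831_01960 (log2 fold change -8.96, SE 0.27, adjusted p = 6.68e-245) in the authors' deposited table. The lower runs with the largest summed change were loci 2362 to 2379 (16 members, median -3.53), 1038 to 1052 (15 members, median -4.17) and 1083 to 1101 (19 members, median -2.82). Under total-count scaling these medians were -2.44, -3.07 and -1.73. In total there were 47 higher runs with 384 loci and 61 lower runs with 445 loci, against a mean of 25.4 and at most 42 runs in shuffled orders. This count and its direction depended on scaling. With the group totals set equal there were 168 higher and 18 lower runs, and 27 of 1000 shuffles gave as many as these 186 (mean 171.4, at most 193).

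Altogether 3469 of 4221 loci (82.2%) were called at T2 in the authors' deposited table, 1795 higher and 1674 lower in the mix. At a log2 fold change of at least 2, 284 loci were higher and 608 lower in the authors' deposited table. Both splits depended on scaling. With the group totals set equal, 2917 of 3760 calls were higher in the mix, and at a log2 of at least 2 there were 1061 higher and 290 lower. The 100 strongest loci held 66.3% of the estimated normalized counts in glucose at T2 and 47.7% in the mix at T2. A few strong loci thus weigh heavily in the totals that this scaling sets equal, and all other loci are moved with them. Which scaling is closer to the cells was not tested.

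Medium effects at the 2 times were also compared directly. A change with time in glucose alone can make them differ. Such a difference does not by itself show phases in the use of the mix. The effect differed in 3190 of 4221 loci, by the z test with Benjamini-Hochberg adjustment. It was higher at T2 in 1609 and lower in 1581, or, with the group totals set equal, higher in 3093 of 3684. The 8 runs higher in the mix at T1 parted into 2 kinds. In 5 of them (loci 338 to 347, 3657 to 3661, 3776 to 3780, 3859 to 3863 and 4035 to 4040) the medium effect of each member was lower at T2. In the other 3 (loci 941 to 949, 2415 to 2419 and 2422 to 2431) the effect of each member was higher at T2. The last 2 of these are parts of 1 longer stretch. All 18 loci from 2415 to 2432 were called higher in the mix at T1, and the 2-fold threshold split them.

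The first kind lost its transcripts in the mix with time. The median level of loci 3776 to 3780 was 17899 normalized counts in the mix at T1 and 475 at T2, and in glucose it was 490 and 581. For loci 338 to 347 the median went from 11127 in the mix at T1 to 850 at T2, and for loci 4035 to 4040 from 5586 to 1144. At T2 the median medium effects of these 3 runs were -0.11, -0.51 and -0.30, and under total-count scaling they were above 0, at 0.99, 0.58 and 0.80. In loci 4035 to 4040, 3 members were called higher and 3 lower in the mix at T2. The medians of loci 3657 to 3661 and 3859 to 3863 at T2 were -1.03 and -1.17, or 0.07 and -0.07 under total-count scaling. Loci 3657 to 3661 and 3859 to 3863 also fell with time in glucose, by median log2 changes of -4.61 and -2.81, less than the -7.45 and -5.85 in the mix. Members of all 5 runs fell in the mix in the authors' deposited table, 30 of 30.

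The second kind gained transcripts. Loci 2422 to 2431 had a median level of 1702 normalized counts in the mix at T1 and 65152 at T2, and of 364 and 713 in glucose. For loci 941 to 949 the median went from 1189 to 47071 in the mix.

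Of the 148 loci at least 2-fold higher in the mix at T1, 55 were so at T2 too, where independent lists would share 33.4. Of the 165 lower at T1, 95 were lower at T2, against 43.9. Under total-count scaling the list higher at T2 went from 952 to 2289 loci and the lower list from 1123 to 572. The overlaps under that scaling are not given here. The medium effects at T1 and T2 correlated across loci with Pearson's r = 0.317 and Spearman's rho = 0.397. Loci are not independent replicates, and no library entered both effects.

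**Figure D2:**
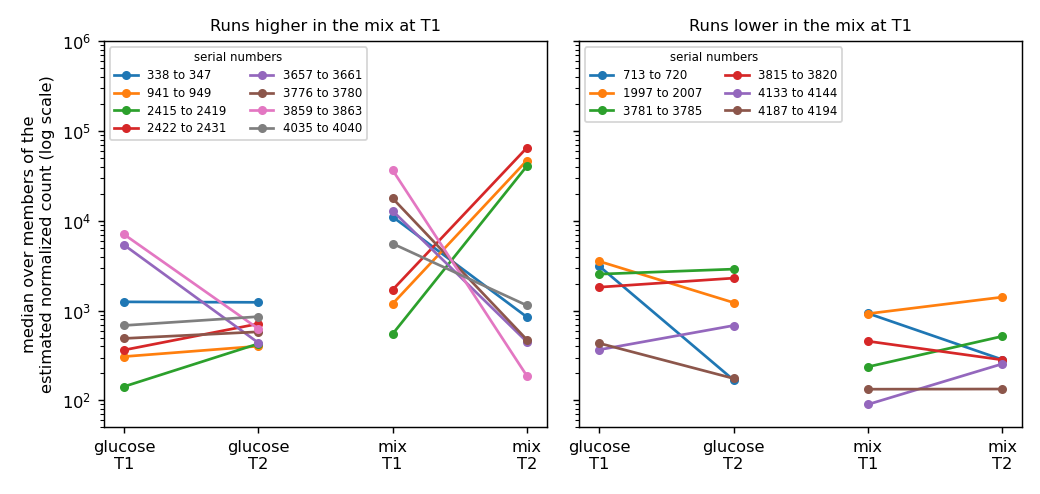
Median over the members of each run of the estimated normalized count (vertical axis, log scale) in the 4 groups (horizontal axis), for the 8 runs higher (left) and the 6 runs lower (right) in the mix at T1, 1 colour per run, with lines joining T1 and T2 of a medium and no error bars because the levels are group estimates. On the left, 3 runs rise in the mix and 5 fall, such as loci 3776 to 3780 from 17899 to 475.

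Changes between T1 and T2 within the mix ask how expression moved as the polysaccharide cultures aged. The strongest rises were those of Alt831_00890 (log2 fold change 8.35, SE 0.42, adjusted p = 1.15e-88) and Alt831_03996 (log2 fold change 7.99, SE 0.27, adjusted p = 2.93e-196) in the authors' deposited table. The strongest falls in the authors' deposited table were those of Alt831_03658 (log2 fold change -8.64, SE 0.47, adjusted p = 3.23e-73) and Alt831_03861 (log2 fold change -8.46, SE 0.57, adjusted p = 3.20e-49). Loci 2409 to 2432 rose by a median log2 of 5.06 over 23 members, loci 941 to 954 by 5.31 over 14 and loci 3987 to 3997 by 6.10 over 11. Loci 3645 to 3661 changed by a median of -6.15 over 17 members, loci 3855 to 3875 by -3.47 over 19 and loci 3522 to 3539 by -2.20 over 18. In all, 3349 of 4221 loci were called in the authors' deposited table, 1671 higher and 1678 lower at T2, and 2229 of 3383 were higher under total-count scaling.

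The same contrast was made in the glucose cultures, where growth and the use of glucose may also differ between the times. Neither is in the values used here. Here Alt831_00918 (log2 fold change 10.26, SE 0.39, adjusted p = 1.04e-147) and Alt831_01960 (log2 fold change 10.003, SE 0.27, adjusted p = 3.31e-300) rose most in the authors' deposited table. The same 2 loci had the largest falls in the mix against glucose at T2. The largest falls with time in the authors' deposited table were those of Alt831_02881 (log2 fold change -5.90, SE 0.41, adjusted p = 1.17e-46) and Alt831_04007 (log2 fold change -5.70, SE 0.49, adjusted p = 9.98e-31). Loci 1031 to 1052 rose by a median log2 of 4.06 over 22 members, loci 1083 to 1111 by 2.86 over 27 and loci 3987 to 4000 by 6.25 over 14. Loci 3645 to 3661 changed by a median of -4.61, loci 3522 to 3539 by -3.89 and loci 360 to 370 by -4.91. Calls reached 3619 of 4221 loci (85.7%) in the authors' deposited table, 1847 higher and 1772 lower at T2, and under total-count scaling 1108 of 3797 were higher.

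The changes with time were then set side by side. Of the 2939 loci called in both media, 1246 rose in both and 1291 fell in both, which is 86.3%, while 209 rose in glucose and fell in the mix and 193 did the opposite. With the group totals set equal, 2052 of 3053 loci (67.2%) moved the same way. Among the loci that moved the same way as deposited, 1936 (76.3%) had the larger change in glucose. The standard deviation of the log2 fold changes was 1.59 in the mix and 2.25 in glucose. Across loci the 2 changes correlated with Pearson's r = 0.645 and Spearman's rho = 0.712, with no library in common and with loci that are not independent replicates.

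A difference between media at T2 can come with a change in either medium since T1. Of the 1123 loci at least 2-fold lower in the mix at T2, 928 rose at least 2-fold with time in glucose and 122 fell in the mix. Independent lists would share 355.7 and 205.7. Of the 952 loci higher in the mix, 728 fell in glucose, 135 rose in the mix and 348 fell in the mix, where independent lists would share 269.1, 188.3 and 174.3. These counts depended on scaling. With the group totals set equal, 495 of 572 lower loci rose in glucose and 33 fell in the mix, and of 2289 higher loci 1837 fell in glucose, 492 rose in the mix and 320 fell in the mix. Unchanged groups give almost no calls of this size, so measurement error in the shared libraries was examined through covariances instead. This choice was made after the values were seen. Across loci, the covariance of the medium effect at T2 with the change in glucose was -3.02, and simulated unchanged groups that share the glucose T2 libraries gave -0.0210. With the change in the mix it was -0.158, against 0.0183. These simulations hold measurement error only. Glucose at T2 enters the medium effect and the change in glucose with opposite signs. A real change in glucose therefore makes their covariance negative by itself, and its size does not tell what set the media apart. Independent lists are no baseline for lists that share libraries, and part of the overlap of calls may come from that sharing.

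With time, the regions named for T2 moved in different ways. Loci 2362 to 2379 rose in glucose in 16 of 16 members, and in the mix 9 rose and 6 fell. Loci 1038 to 1052 rose in glucose in 15 of 15 members, and in the mix 10 rose and 2 fell. Loci 2415 to 2432 rose in the mix in 18 of 18 members, and 13 of these also rose in glucose. Their median log2 change was 5.21 in the mix and 1.13 in glucose, or 5.58 and 0.05 under total-count scaling. Of the 21 members of loci 932 to 955, 13 rose and 8 fell in the mix, and 8 rose and 11 fell in glucose. Within them, loci 932 to 939 formed a run that fell in glucose, by a median log2 change of -3.65 against -1.65 in the mix, while loci 941 to 954 formed a run that rose in the mix. Of the 16 members of loci 3263 to 3278, 13 rose in the mix, and 1 rose and 0 fell in glucose, where the median change was -0.01, or -1.09 under total-count scaling. Loci 1083 to 1101 rose in glucose in 19 of 19 members, and 15 rose in the mix.

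**Figure D3:**
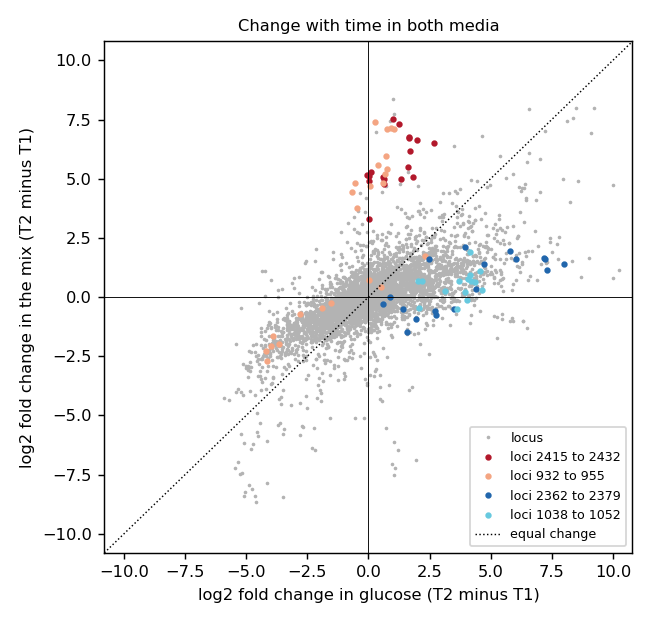
Log2 fold change of T2 minus T1 in the mix (vertical axis) against that in glucose (horizontal axis), 1 grey point per locus, with the 2 runs of largest summed medium effect at T2 in each direction in colour and a dotted line at equal change. Loci 2415 to 2432 lie far above the line, loci 1038 to 1052 lie below it, and r is 0.645 over all loci.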

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

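The tests of scaling, of depth and of read spill-over, and the choice of total-count scaling, were made after the results were seen. The test of gene order was written before its result was seen.

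The effect of the medium differed between T1 and T2 in 3190 loci by the test of the difference. In 52 loci the media differed at least 2-fold in opposite directions at the 2 times, 37 of them higher in the mix at T1 and lower at T2, and 15 the other way. Independent lists would share 39.4 and 37.2, and under total-count scaling the counts were 8 and 86, against 13.0 and 190.3. Without a fold threshold, 353 loci were called in opposite directions at the 2 times. For this count, neither the number that independent lists would share nor the value under total-count scaling is given here. No excess of reversals can therefore be read from it. Of the runs higher in the mix at T1, 5 had a lower medium effect at T2 in each member, by the test of the difference. By the same test 3 had a higher one in each member, and 2 of these 3 are parts of 1 stretch, loci 2415 to 2432. Under total-count scaling the median change of the medium effect kept its sign in all 8 runs, and was smallest for loci 3657 to 3661 (-0.83, against -2.29).

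More loci differed between media at T2 than at T1. A shift in scaling cannot change the spread of the fold changes, and their standard deviation at T2 was 2.55 times that at T1, above the bound of 1.5 set for scaling as the whole cause. Greater depth at T2 needs more counts per library there, but the estimated counts per library at T2 were 0.894 times those at T1. Both argue against these technical causes. Other technical causes, such as RNA quality or a library batch, could not be examined without values per library and stay open. A biological difference that grows with time, such as a different growth phase of the 2 media at 21 h, also stays open. It was not tested.

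Loci that differed between media lay side by side. Of the 1000 shuffles, 0 gave as many runs as the 14 at T1, which argues against a chance order of the loci at T1 (with total-count scaling, 19 runs against at most 2). For reads spilling over from 1 strong locus into its neighbours, a bound of 5% was assumed. Members at least 2 places from the member with the largest rise in level over glucose would stay under 5% of its rise. Their median rise at T1 was 24.3% of it, over 32 members of the higher runs (quartiles 7.18% and 45.6%), and 5 members were under 5%. Each member had to be called at least 2-fold higher to be in a run, so loci with little rise were left out beforehand. How far reads spill was not measured. The values therefore do not decide on spill-over. A shared transcript or a shared regulator of neighbouring loci may be the reason, as a hypothesis. Which polysaccharide goes with which run cannot be read from these cultures, since each mix culture held all 3 and the tags carry no names.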

How the results depend on the processing

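Total-count scaling was chosen after the data were seen. No paired analysis was possible because the values are comparison tables without library columns. For the same reason leaving out each replicate, other splits of the libraries, another count tool and other pseudocounts were not run, nor were the settings for gene lists. Counts of called loci stayed within 1.5 times the main count in 30 of 37 alternatives. Some of these could not differ. Adjustment over every locus with a p repeats the deposited adjustment, and the median for time in the mix was already 0. The difference taken from the tables over time is the same quantity. Asking for a log2 fold change of at least 1 lowered the calls to 313 (media at T1), 2075 (media at T2) and 1608 (time in the mix), from 1645, 3469 and 3349, and at least 2 lowered them to 97, 892, 547 and, for time in glucose, 1379 from 3619, by construction. An adjusted p under 0.01 gave 1216, 3269, 3082 and 3439 in the order media at T1, media at T2, mix and glucose, and 2921 for the difference of the medium effects. The number of runs stayed within 1.5 times in 7 of 12 alternatives. At a log2 of at least 2 there were 5, 33, 16 and 63 runs, in the same order, in place of 14, 108, 80 and 139, since fewer loci qualify. Total-count scaling gave 186 runs for the media at T2, where 2289 loci were at least 2-fold higher in the mix in place of 952. Shuffled orders of these calls gave a mean of 171.4 runs, so most such runs arise from the number of calls alone. All 32 recomputed values of named loci kept their direction and stayed past the threshold, with the median set to 0 or with total-count scaling. These loci were picked for changes far larger than the shifts, so their direction could not turn. Low counts limit precision in the 88 loci with a mean normalized count under 50, whose median standard error was 0.358, against 0.142 in the others.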

Other observations

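The loci and regions of this part, and its tests of possible causes, were chosen after the results were seen. The calls, the runs and the test of the difference follow the rules fixed beforehand.

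A few loci took a large share of the transcripts in late glucose cultures. The 10 strongest loci held 11.3% of the estimated normalized counts in glucose at T1 and 36.2% at T2, and in the mix 12.4% and 22.7%. Alt831_00817, singled out after its values were seen, held 2.22% in glucose at T1, 10.6% in glucose at T2, 2.10% in the mix at T1 and 5.96% in the mix at T2. In the authors' deposited table it rose with time by a log2 of 3.34 (SE 0.13, adjusted p = 5.28e-148) in glucose and 1.13 (SE 0.13, adjusted p = 4.36e-18) in the mix. The total of normalized counts in glucose at T2 was 2.12 times that in glucose at T1.

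Some regions moved in the same direction in both media. Loci 3987 to 3997 rose with time in each of 11 members in both media, by a median log2 of 6.10 in the mix and 7.01 in glucose. Loci 3645 to 3661 fell in each of 17 members in both, with median log2 changes of -6.15 in the mix and -4.61 in glucose. In 16 of these members the medium effect was lower at T2. The median difference over the run was -1.62, or -0.16 under total-count scaling. Loci 360 to 370 also fell in all 11 members in both media, and less in the mix, with a higher medium effect at T2 in each.

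Time changes in the mix were smaller than those in glucose, with a ratio of their standard deviations of 0.707. Over the 2521 loci with a mean normalized count of at least 1000 the ratio was 0.715, which argues against loci with few counts as the cause. If 1 common set of changes were scaled down in the mix, the changes of both media would follow each other closely, and measurement error alone would allow an r of 0.988. The observed r was 0.645, so a common set of changes is at most part of the pattern. A slower or later course of growth on the mix may contribute and was not tested, since growth data were not used here.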
